A study of Danio rerio with 2 samples.

How the data were processed

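Brains of zebrafish larvae at 7 dpf were profiled by droplet single-cell RNA sequencing in 2 libraries, 1 from food deprived larvae and 1 from larvae fed paramecia. Per the labels, the larvae carried a Gal4FF driver and a UAS:GCaMP6s reporter and were chosen by GCaMP6s signal in the lateral part of the hypothalamus. Brains of 50 larvae per group were dissociated with papain in the presence of actinomycin D, which blocks transcription. Sorted GCaMP6s-positive cells made up 50% of the cells loaded and GCaMP6s-negative cells the rest. Libraries were made with the Chromium 3' chemistry. According to the submitters' processing notes, reads were processed with Cell Ranger against the GRCz11 assembly, and no software versions are given in the sources used here.

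The deposited matrices hold an estimated count of UMIs per gene and barcode, as the authors' processing left it, with no log scale and no scaling between cells. Of the entries above 0, 1.16% in each library were not whole numbers, and these lay in 446 gene symbols that stand for several gene models. Fractional UMIs made up 0.575% of the food deprived library and 0.584% of the fed library. Counts were summed as they stand, and sums were rounded to whole numbers for counting intervals only. The files list 24826 features, of which 24825 are genes or transgenes. The remaining feature names no gene and was left out, at 0.00175% and 0.00176% of the UMIs of the food deprived and fed libraries.

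Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrially encoded UMIs were kept. This left out 5 barcodes of the food deprived library and 15 of the fed library. Scrublet called 1 doublet among 4416 food deprived cells (0.0226%) and 0 among 4613 fed cells. These calls lay under the 0.5% set beforehand as the level for removal, so no cell was removed as a doublet. Doublets that the caller missed remain among the cells, and whether doublets had been removed before deposit is not given in the sources used here. Cells were normalised to 10000 UMIs and log transformed, 2000 variable genes were ranked within each library, and the growth hormone, tachykinin and immediate early lists were taken out of them, which left 1967. The analysis used 30 principal components without integration of the libraries, 15 nearest neighbours, a shared-neighbour Jaccard graph and Leiden clustering at resolution 1 with a fixed seed.

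Clusters were named from 29 marker sets. A cluster was called neuron-like when at least 9 of 15 neuron markers were each found in at least 25% of its cells, and other classes needed at least 3 markers of their set at a log2 ratio of at least 1 over the other cells, at least 1 of them among the 10 leading genes. The restriction of leading genes to those in at least 10% of a cluster's cells and the minimum of 9 neuron markers were both set after the clusters had been examined. They decide the naming of cluster 3 (346 food deprived and 415 fed cells, 7.84% and 9.00% of the libraries) and of cluster 14 (97 and 60 cells, 2.20% and 1.30%).

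Fed was compared with food deprived by summing UMIs over the cells of a class in each library and dividing by that class's total, as counts per 1000000 UMIs (CPM). Each CPM has an exact Poisson 95% interval, each log2 ratio (fed minus food deprived) an exact conditional binomial 95% interval, and each share of cells an exact Clopper-Pearson 95% interval. With 1 library per group these intervals cover counting error only, no test between groups was made, and cells were not treated as replicates. Ratios were computed with 0.5 UMIs added to each sum, and a count of 0 is given with the limit that 3 counts would set. Shares of cells with a UMI are given with all UMIs and with each cell thinned to 1000 UMIs, which leaves out shallower cells.

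The comparisons, the filters, the marker sets, the gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. By that rule the genes named in neurons are the 12 with the highest and the 12 with the lowest log2 ratio among genes with at least 300 UMIs. The 6 highest and 6 lowest are named in each other class with at least 200 cells in each library and in all cells. Clone-type names, mitochondrially encoded and ribosomal protein genes and markers of blood, photoreceptor, epidermal, muscle, pituitary, leukocyte, microglial and fibroblast cells took no place, nor did the transgenes. All measured tachykinin genes and the growth hormone receptors are named, and of each other list the 4 members with most UMIs and the 2 with the largest ratio among those with at least 100 UMIs were drawn on. Not every gene the rule takes is repeated in the text. Genes in at least 10% of the neurons of either library, the groups of neurons with at least 5 Gal4FF UMIs or none, for which 12 genes per direction were taken, and the comparison of tac1-positive with tac1-zero cells were chosen after the data were examined.

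The 15 gene lists cover the growth hormone axis, the tachykinin system, orexigenic and anorexigenic neuropeptides, immediate early genes, glucocorticoid response, integrated stress response and amino acid scarcity, insulin, FOXO and fasting metabolism, sterol synthesis, heat shock and protein folding, the circadian clock, synaptic transmission, mitochondrially encoded genes, nuclear oxidative phosphorylation and ribosomal proteins. Each list's median log2 ratio over members with at least 20 UMIs was placed among 10000 random lists of the same size drawn from 20 expression bins. The percentile describes these 2 libraries and is not a test between groups. The pattern for ribosomal proteins also takes 12 genes that are not ribosomal proteins, 11 kinases of the rps6k family and rps19bp1.

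The alternative settings fixed then were median-of-ratios scaling, a total without hormone, haemoglobin, mitochondrially encoded and ribosomal protein genes, all deposited barcodes, a stricter cell filter (1000 UMIs, 600 genes, 10% mitochondrially encoded), other clustering resolutions (0.5 and 2) and all variable genes. Pooling was also varied, with clusters weighted equally, as were the thinning depth (500, 1000 and 2000 UMIs per cell) and the UMI minimum for list members. Cells with a pou1f1, prl, pomca or cga UMI were left out in a further setting. Alternatives chosen after seeing the data left out the 5% of cells with most UMIs, the transgenes from the variable genes, the 3 cells with most UMIs of each gene, or cluster 3 or 14. Others added then changed the Gal4FF and tac1 minimums, the cells in which ghra was read, and the weighting of clusters among Gal4FF-high and among GABAergic-like neurons. The 3 top cells of named genes were left out then also in GABAergic-like neurons and in all cells.

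The procedure was tested on simulated data for the comparison of all cells, with Poisson counts drawn from the pooled expression of both libraries at their depths and known changes put into 50 of 10048 genes per size. Log2 changes of -1, -0.5, 0.5 and 1 were recovered with medians of -1.01, -0.48, 0.50 and 1.02, and the intervals covered the true change in 96%, 100%, 94% and 100% of genes. Among 9848 unchanged genes 95.3% of intervals covered 0, and 94.5% of 200 unchanged lists fell in the middle 95% of their random lists. The simulated counts had no variation between cells or libraries beyond Poisson error. Coverage near 95% therefore follows from the way they were drawn, and says nothing of genes whose UMIs are gathered in few cells. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.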

Results

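The series compares single cells from the brains of larval zebrafish that were kept without food for 4 h with cells from larvae that were then given paramecia for 30 min. Its title names growth hormone and tachykinin in feeding. The food deprived library held 4421 barcodes and 21879722 UMIs, and the fed library 4628 barcodes and 22799389 UMIs. After filtering, 4416 food deprived cells had a median of 3901 UMIs and 1732 genes, and 4613 fed cells had 4021 UMIs and 1718 genes. Mitochondrially encoded transcripts took a median of 1.14% and 1.12% of a cell's UMIs. Each group has 1 library, so values are given for these 2 libraries with counting intervals, and no difference between groups was tested.

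Most cells were neuron-like, 83.9% of the food deprived library (95% interval 82.7 to 84.9%) and 82.8% of the fed library (81.7 to 83.9%). The 28 clusters held 16 neuron-like clusters, among them GABAergic-like clusters with 22.5% and 24.04% of the cells, marked by the glutamate decarboxylase genes gad2 and gad1b. Smaller groups were radial glia-like (110 food deprived and 135 fed cells), oligodendrocyte precursor-like (87 and 59), microglia-like (39 and 24), oligodendrocyte-like (20 and 21) and glutamatergic-like habenular cells (31 and 37). A monoaminergic-like cluster, led by tph1a, chgb and scgn, held 97 and 60 cells. Clusters with no name held 450 and 516 cells, and cluster 8 among these was led by the Notch pathway genes dla and her4.2. The unnamed cluster 13 (95 and 132 cells) had 4 epidermal-set markers, icn, krt4, cyt1 and anxa1a, among its leading genes. An epidermal-like cluster was 85.2% fed cells (4 and 23 cells) and an erythrocyte-like cluster 84.2% fed cells (3 and 16 cells), so these mainly describe the fed library. Neuron-like cluster 9 was led by atf5b, atf5a and ddit3, which are stress response genes. Because sorted positive and negative cells were mixed before loading, shares also reflect the sort.

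Among genes found in many neurons, fkbp5 and klf9 had the highest ratios of fed over food deprived, and cox8b and glrx the lowest. The 2 libraries differ by design in 30 min of feeding, and other differences between them are not excluded. Among 4765 genes in at least 10% of the neurons of either library, fkbp5, a co-chaperone induced by glucocorticoids, was the highest in the fed library at 126.9 CPM against 45.5 CPM, a log2 ratio of 1.48 (1.36 to 1.61). The glucocorticoid-responsive transcription factor gene klf9 followed at 1.21 (1.00 to 1.41). Next came ucp2, a mitochondrial uncoupling protein gene, at 0.92, itm2cb at 0.89, pfkfb4b, which encodes a regulator of glycolysis, at 0.75, nocta (nocturnin) at 0.68 and pik3r3a, a regulatory subunit of phosphoinositide 3-kinase, at 0.66. The remaining genes of this kind were abcf2a (0.65), nfil3-6 (0.64), the AP-1 family genes jdp2b (0.57) and atf3 (0.55), and the co-chaperone gene bag3 (0.55).

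At the other end of the same set, lower in the fed library, were cox8b, a cytochrome c oxidase subunit gene, at -0.85 (-0.98 to -0.72), and glrx (glutaredoxin) at -0.83 (-1.03 to -0.64). The prostaglandin D synthase genes ptgdsb.1 and ptgdsb.2 stood at -0.60 and -0.58, ddt at -0.54, her6 at -0.51, dpp7 at -0.48, znf503 at -0.47, shox2 at -0.47, chchd10 at -0.42, mpv17l2 at -0.41 and rabl2 at -0.41. With clusters weighted equally ddt was at -0.32 and her6 at -0.19, and with cells thinned znf503 was at -0.21. shox2 is a leading gene of cluster 7, which held 318 food deprived and 217 fed cells. Among the higher genes, itm2cb is a leading gene of neuron-like cluster 16, which held 41 food deprived and 72 fed cells. The middle 95% of these genes lay between -0.23 and 0.30, and these 24 genes were picked after their values had been seen.

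**Figure D1:**
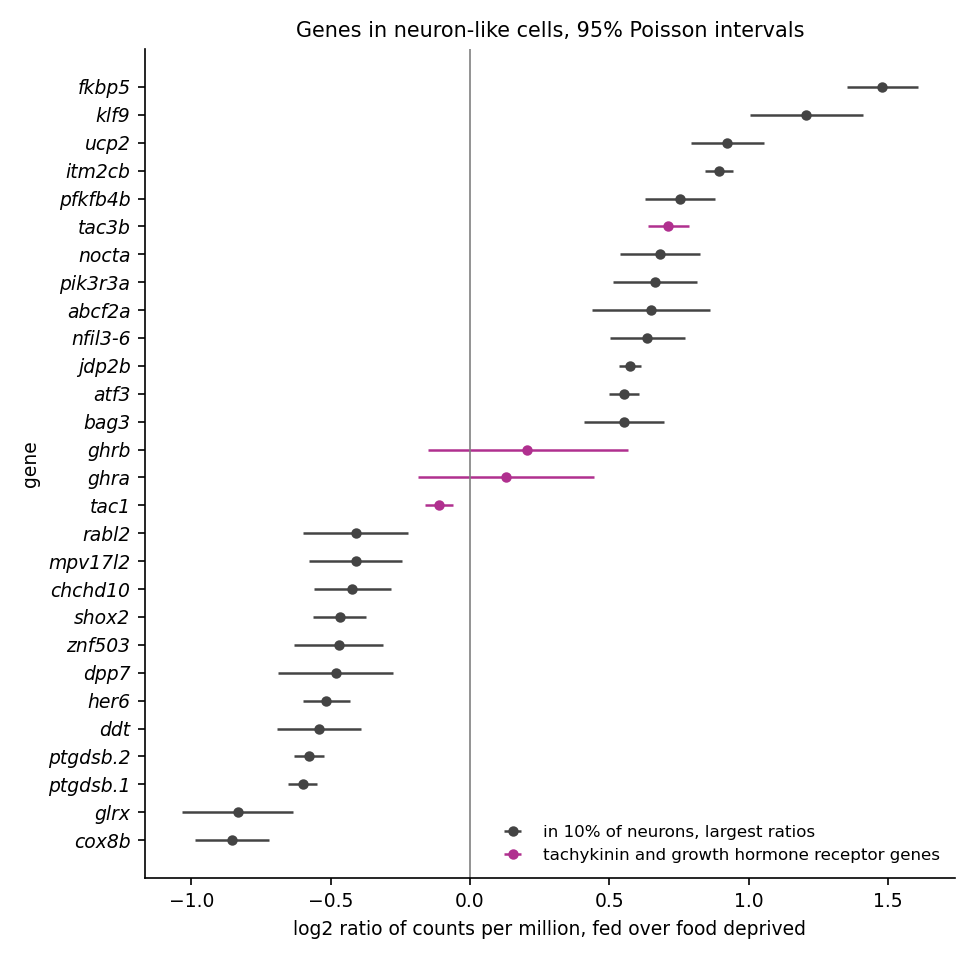
Log2 ratio of CPM in neuron-like cells, fed over food deprived, for the 24 genes in at least 10% of neurons with the highest and lowest ratios and for tachykinin and growth hormone receptor genes, with 95% Poisson-based counting intervals as bars. fkbp5 stands highest at 1.48 and cox8b lowest at -0.85, while ghra and ghrb have intervals that include 0.

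Without a minimum number of cells, many of the largest ratios were those of neuropeptide genes, and most rested on few cells. Of 8502 genes with at least 300 UMIs, the highest in the fed library was cart1, a cocaine- and amphetamine-regulated transcript gene, with 1 UMI against 1482, all of the latter in 5 cells, a log2 ratio of 9.87 (7.98 to 15.76). gnrh3 had 3 UMIs against 1602 (8.76, 7.43 to 11.26), CARTPT 8 against 2004 (7.81), npffl 3 against 764 (7.69, 6.36 to 10.20), gnrh2 74 against 6204 (6.30) and the spexin gene spx 77 against 1122 (3.78). The remaining 6 were c16h2orf66 (3.39), prlh (2.22), npvf (1.88), adcyap1a (1.65), npb (1.58) and pmch (1.51). Lower in the fed library were agrp, the agouti-related peptide gene, with 698 UMIs in 4 cells against 3 UMIs (-7.72, -10.22 to -6.39), pmchl, a melanin-concentrating hormone gene, with 33302 against 4097 UMIs (-3.10), and avp, with 6019 against 805 UMIs (-2.98). The rest of this group were rgcc (-1.36), kiss2 (-1.30), pde6gb (-1.12), the glycine transporter gene slc6a5 (-1.09), scgn (-1.06), ndufa4l2a (-1.05), the serotonin synthesis gene tph2 (-0.99), vipb (-0.94) and sncga (-0.92). In 21 of these 24 genes over 50% of the UMIs of the higher library lay in 5 cells or fewer. The exceptions were scgn (17.4%, read in 170 and 128 neurons), ndufa4l2a (28.0%) and tph2 (30.2%). With the 3 cells with most UMIs of the gene left out in each library, CARTPT and pmch were both at -0.08 and pde6gb at 0.02. For CARTPT and pmch the counts left were equal in both libraries, so -0.08 is only the ratio of the UMI totals. Without the 5% of cells with most UMIs pmchl was at 0.49 and CARTPT at -0.46, each the opposite sign. Without cluster 14, scgn was at -0.26 and ndufa4l2a at 0.22.

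Immediate early genes, transcripts induced within minutes of neuronal activity, were higher in the fed library in 34 of 41 measured members, with a median log2 ratio of 0.27, above all 10000 random lists. fosab stood at 4426 CPM against 3517 CPM (0.33, 0.32 to 0.35) and npas4a at 1719 against 1232 CPM (0.48, 0.45 to 0.51). egr4 was at 0.17, gadd45ba at 0.13, egr2a at 0.98 and csrnp1a at 0.65. egr2a is a leading gene of cluster 16, which held 41 food deprived and 72 fed cells. The glucocorticoid response list was higher in 9 of 14 members with a median of 0.21 (percentile 100), and 0.09 with cells thinned. Beside fkbp5 and klf9, the abundant members nr3c1 (0.11), zbtb16a (-0.01) and mt2 (-0.10) lay close to 0. With clusters weighted equally nr3c1 was at -0.01 and mt2 at 0.23. Insulin, FOXO and fasting metabolism genes were higher in 17 of 23 members with a median of 0.11 (percentile 99.7), including the insulin receptor substrate gene irs2b at 0.40 (0.33 to 0.48), foxo3a at 0.16, ppargc1b at 0.13 and sesn1 at 0.09, with angptl4 at -0.43. Synaptic transmission genes were higher in 23 of 33 members (median 0.05, percentile 98.1, or 0.00 with clusters weighted equally), with grin2bb at 0.32, cplx2 at 0.20, syt1a at 0.13 and snap25a at -0.05.

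Orexigenic neuropeptide genes were lower in 7 of 11 members, with a median of -0.27 that lay below all random lists. Its members went both ways, and agrp, pmchl and galn had at least 85.8% of the UMIs of the higher library in 5 cells or fewer. npy was at 0.39 (0.32 to 0.46), galn at -0.27 (-0.35 to -0.19) and pdyn, read in 202 and 208 neurons, at -0.09 (-0.18 to 0.00), beside agrp and pmchl. The median turned to 0.12 with cells thinned to 1000 UMIs, where galn was at 1.06, and was -0.10 with clusters weighted equally and -0.09 without the 5% of cells with most UMIs. Anorexigenic neuropeptides had a median of 0.02 (13 of 26 higher, percentile 69.5), with ccka at -0.27 (-0.32 to -0.23; 0.32 in Gal4FF-high and -1.78 in Gal4FF-zero neurons), adcyap1b at -0.13, cckb at -0.08 and nucb2a at 0.07. The median was -0.10 without the 5% of cells with most UMIs and 0.10 without cluster 3.

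Nuclear oxidative phosphorylation genes were lower in 26 of 35 members (median -0.06, percentile 0.49), with cox6b1 at -0.24, cox4i1 at -0.10 and cycsb at 0.14. Within Gal4FF-high neurons they were higher in 21 of 35 members (median 0.02, percentile 64.5), inside the range of random lists. Mitochondrially encoded genes were lower in 10 of 13 members (median -0.06), within the range of random lists (percentile 11.9), with mt-nd1 at -0.20 and mt-cyb at -0.14. Ribosomal protein genes were lower in 71 of 92 members (median -0.06, percentile 0), with rplp1 at -0.09 and rpl26 at -0.66. Without the rps6k kinases and rps19bp1 it was 64 of 80 members (median -0.06, percentile 0.01), and with clusters weighted equally the median of the full list was -0.01.

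The other lists lay within the middle 95% of random lists. Heat shock and protein folding genes had a median of 0.06 (percentile 95.4), or 0.14 with clusters weighted equally, with hsp70l at -0.01, hsp90ab1 at -0.05, hsp90aa1.2 at 0.22 and hspb1 at 0.95. The integrated stress response list had 0.03 (percentile 78.5), ranging from -0.01 to 0.11 over alternative settings, with ddit3 at 0.20, trib3 at 0.25, slc3a2b at 0.21, chac1 at 0.17 and ddit4 at -0.25. Circadian clock genes had 0.03 (82.8), with clockb at 0.43 and ciarta at -0.20. Sterol synthesis genes had -0.07 (19.8), or 0.11 with cells thinned, with hmgcra at 0.43 (-0.01 to 0.87) and dhcr7 at -0.23 (-0.54 to 0.08). The growth hormone axis had 0.05 (84.4), ranging from -0.05 with clusters weighted equally to 0.16 with cells thinned. The tachykinin system had -0.07 (23.6), or 0.11 with clusters weighted equally.

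**Figure D2:**
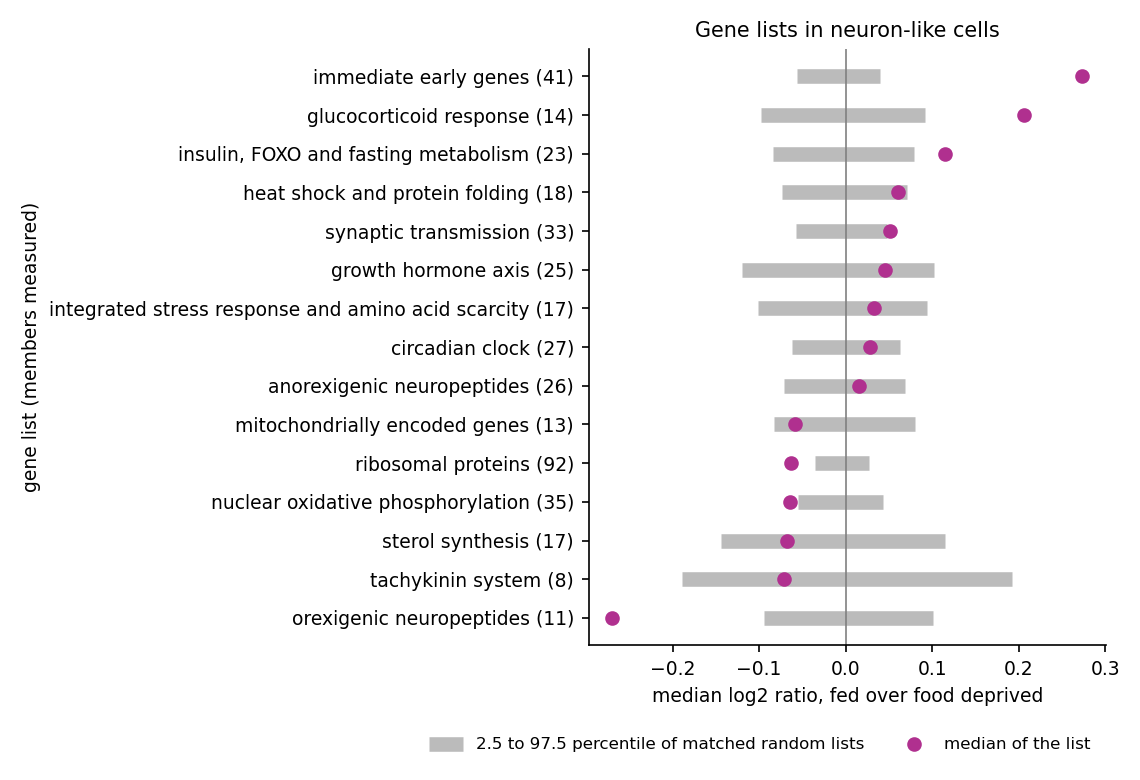
Median log2 ratio, fed over food deprived, of each gene list in neuron-like cells (points), with the middle 95% of 10000 random lists matched on expression (bars) and the number of measured members in brackets. Immediate early genes stand highest at 0.27 and orexigenic neuropeptides lowest at -0.27.

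Markers of blood cells also stood apart in neurons. Haemoglobin genes summed to 3.55 CPM in food deprived neurons and 382.0 CPM in fed neurons, a log2 ratio of 6.74, and were read in 54 of 3703 (1.46%, 1.097 to 1.90%) and 214 of 3819 neurons (5.60%, 4.90 to 6.38%). Leukocyte markers stood at 1.71, epidermal markers at 1.34, photoreceptor or pineal markers at 0.44 and pituitary-set markers at 0.25. Fibroblast markers were at 0.16, muscle markers at 0.12 and microglial markers at -0.47. The pituitary set, with 6356 and 7958 UMIs in neurons, also holds chga, chgb, scg2a and pcsk1. chgb is a leading gene of neuron-like cluster 14, and cga had only 80 and 3 UMIs in all cells. The ratio of that set is therefore not one of pituitary RNA alone. Groups of liver genes and of pigment and skin genes, both chosen after the data were examined, stood at -2.25 (-2.84 to -1.73, 160 against 35 UMIs) and 0.76 (0.33 to 1.22). These values go with every gene group above, since they come from the same neurons.

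Immediate early genes and fkbp5 were higher in the fed library across the neuron clusters measured, all of which came from the same 2 libraries. The immediate early list was higher in 11 of 11 clusters with at least 50 cells in each library, with log2 ratios from 0.03 to 0.50, and in 10 of them the interval lay above 0. fosab was higher in 11 clusters (0.05 to 0.86), npas4a in 11 (0.31 to 1.16) and fkbp5 in 11 (1.19 to 1.79). For npas4a and fkbp5 every interval lay above 0, and for fosab 10 did. In GABAergic-like cluster 6 the list stood at 22962 CPM in the food deprived library and 29277 CPM in the fed library, a log2 ratio of 0.35. Cerebellar granule-like cluster 11 and monoaminergic-like cluster 14 were both at 0.50, and cluster 5 was at 0.03 (-0.03 to 0.09).

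**Figure D3:**
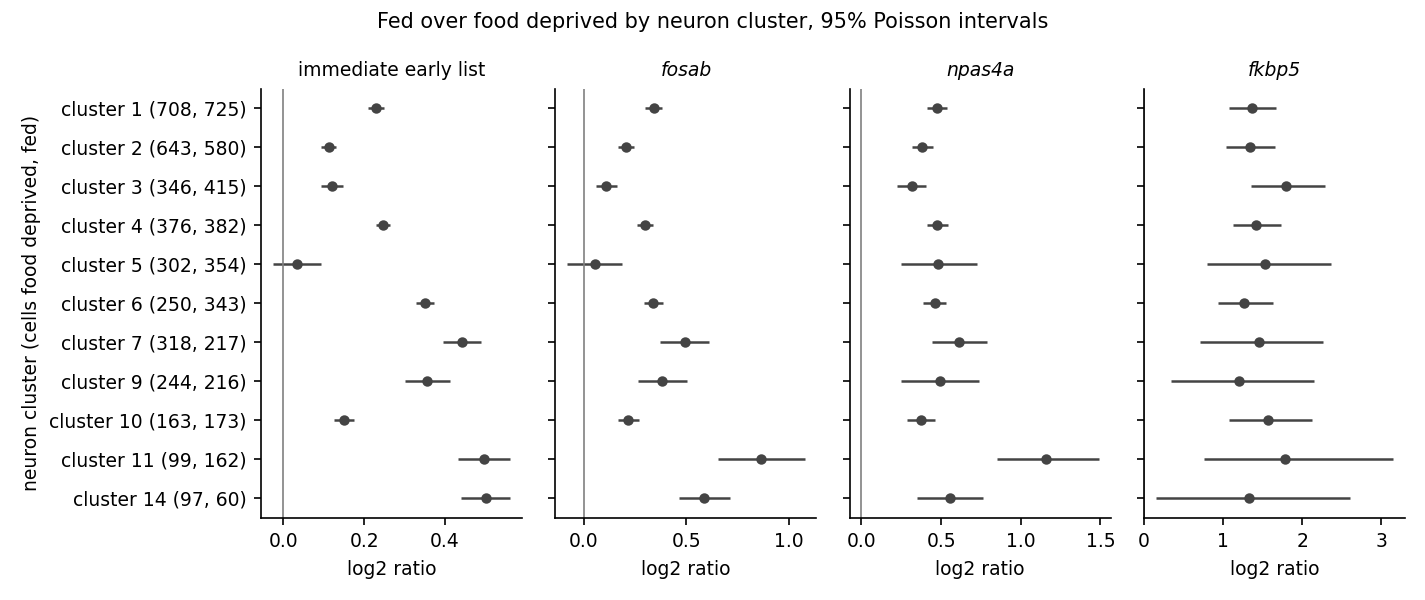
Log2 ratio of CPM, fed over food deprived, in each neuron cluster with at least 50 cells per library, for the summed immediate early list and for fosab, npas4a and fkbp5, with 95% counting intervals. All points lie above 0, and fkbp5 ranges from 1.19 to 1.79.

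The tachykinin gene tac1, which encodes the substance P precursor, was close to equal in neurons of both libraries, at 440.6 CPM and 408.1 CPM (log2 ratio -0.11, -0.16 to -0.06), and at -0.22 with clusters weighted equally. The neurokinin B precursor genes tac3a and tac3b stood at 0.17 (0.08 to 0.27) and 0.71 (0.64 to 0.79), the latter at 154.6 and 253.3 CPM, and tac3a was at -0.13 with cells thinned. A tac3b UMI was read in 92 and 96 neurons (2.48% and 2.51%). In cluster 3 tac3b had 260 and 1103 UMIs in 11 and 14 cells, and in cluster 1 535 and 1164 UMIs in 16 and 18 cells. Other clusters went the other way, such as cluster 6 with 98 and 6 UMIs. The receptor genes tacr1a (-0.19), tacr1b (-0.73), tacr2 (0.07), tacr3a (-0.24) and tacr3l (-0.03) each had an interval that included 0, and tac4 had 0 UMIs. The growth hormone receptor genes ghra at 0.13 (-0.19 to 0.45) and ghrb at 0.21 (-0.15 to 0.57) showed no difference detectable at this depth in neurons. Over all cells ghrb was higher in the fed library at 0.59 (0.36 to 0.81), with 273 against 427 UMIs. Its level in cluster 22 was 279.6 CPM in the food deprived and 655.0 CPM in the fed library, in 57.1% and 89.7% of 28 and 29 cells. Part of the rise came with unequal numbers of cells, as in the epidermal-like cluster 27, where 4 food deprived cells had 1 ghrb UMI and 23 fed cells had 27. Clusters 10, 12 and 13 had 18 and 33, 13 and 28, and 29 and 48 UMIs. Growth hormone gene gh1 and its pituitary transcription factor pou1f1 had 0 UMIs in all cells, which limits the UMIs assigned to each to 0.137 CPM in the food deprived and 0.132 CPM in the fed library and to 0.0679% and 0.0650% of cells with a UMI. Whether the pituitary was dissected and whether the 3' end of each gene is annotated were not examined here, so this sets no limit on expression. Other pituitary hormone genes were rare, with prl at 1 and 2 UMIs, pomca at 0 and 2, and cga at 80 UMIs in 9 cells and 3 UMIs in 3 cells. igf1 had 6 and 10 UMIs in neurons. The somatostatin genes sst1.1 and sst1.2, of the family that inhibits growth hormone release, were higher in the fed library at 1.199 (1.15 to 1.25) and 1.48 (1.42 to 1.54), and were read in 113 and 198 and in 16 and 49 neurons.

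A tac1 UMI was found in 8.99% of food deprived neurons (8.09 to 9.96%) and 9.56% of fed neurons (8.64 to 10.5%), at median depths of 3726 and 3827 UMIs. With each cell thinned to 1000 UMIs, which left out 81 and 74 neurons, the shares were 6.82% and 6.97%. As background, tac1 was found in 0.851% and 0.712% of cells of the unnamed cluster 8, at 9279 and 8260 UMIs, and in 0 of 39 and 0 of 24 microglia-like cells at 12317 and 11692 UMIs, which allows up to 7.69% and 12.5%. tac1 was concentrated in cluster 10 (47.9% and 44.5% of cells), cluster 6 (38.0% and 35.6%) and the small cluster 26 (16 and 14 cells, 87.5% and 64.3%). It was itself a leading gene of these clusters. ghra was found in 2.84% and 3.04% of neurons, in 21.2% and 18.4% of cluster 6, in 23.6% and 26.7% of radial glia-like cells at 4640 and 4480 UMIs, in 25.3% and 20.3% of oligodendrocyte precursor-like cells, and in 0 microglia-like cells. The deeper unnamed clusters 8 and 24 had it in 22.98% and 16.0% and in 63.3% and 65.0% of cells, the latter at 17646 and 15552 UMIs in 30 and 20 cells.

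In GABAergic-like neurons (995 and 1109 cells), immediate early genes were higher in the fed library in 33 of 39 members (median 0.39, percentile 100). Glucocorticoid response genes were higher in 9 of 13 (0.30, 99.98) and insulin, FOXO and fasting metabolism genes in 16 of 22 (0.22, 99.98). Orexigenic neuropeptides were at -0.23 and oxidative phosphorylation genes at -0.09. The mix of clusters differed, with cluster 6 at 250 of the 995 food deprived and 343 of the 1109 fed cells. With clusters 1 and 6 weighted equally the medians were 0.33 for immediate early and 0.31 for glucocorticoid response genes. That of insulin, FOXO and fasting metabolism genes was 0.25, and tac1 was at -0.36. The named genes were cart4 (75 against 2041 UMIs in 3 and 6 cells, 4.57), synpr (2.57), prlh (2.11), cckb (1.90), npb (1.69) and nmu (1.66), and at the other end urp1 (581 against 2 UMIs, -8.05, -11.42 to -6.51), nppal (-1.43), tph2 (-1.41), rln3a (-1.32), en1b (-1.28, in 107 and 58 cells) and sorcs3b (-1.16). Each of the 6 higher genes had at least 64.8% of the UMIs of the higher library in 5 cells or fewer, as had urp1, nppal and rln3a. For tph2, en1b and sorcs3b it was 30.5%, 16.9% and 15.8%. Without its 3 top cells nmu was at 0.55. urp1 was read in 3 food deprived and 2 fed cells, so none of its UMIs were left. Its value of -0.18 is then only the ratio of the UMI totals. tac1 was at -0.14 (-0.22 to -0.06), tac3a at 1.09 and ghra at 0.07 (-0.30 to 0.45).

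Radial glia-like cells, though fewer than the minimum of 200 cells, went the other way for immediate early genes. Of 35 members 3 were higher in the fed library, with a median of -0.57 (percentile 0), while glucocorticoid response genes were higher in 8 of 11 (0.52, percentile 99.98). Heat shock genes had a median of -0.34 (percentile 0.05) and ribosomal protein genes 0.08 (99.9). Over all cells the immediate early median was 0.14 (33 of 41 higher, percentile 100) and that of oxidative phosphorylation -0.08 (percentile 0.03). The largest ratios over all cells were those of gnrh3 (8.78), cart1 (8.67), s100t (8.02), CARTPT (7.82), npffl (7.72) and s100a11 (7.33), and at the other end the liver genes agxtb (927 UMIs against 1, -9.33, -15.22 to -7.43), serpina1 (519 against 1, -8.49), apoa1b (-8.14), fabp10a (-7.92), serpina1l (532 against 2, -7.79) and apoa2 (-7.71). In each of these 12 genes at least 99.0% of the UMIs of the higher library lay in 5 cells or fewer. Without the 3 top cells of the gene in each library, apoa1b was at -1.78, agxtb at -7.53 and fabp10a at -6.90. serpina1 and CARTPT were then both at -0.06, with equal counts left, which is only the ratio of the UMI totals. A set of 5 abundant liver genes grouped after the values had been seen summed to 1007 and 3.99 CPM.

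Neurons with at least 5 UMIs of the Gal4FF driver made up 28.3% of food deprived neurons (1049 cells, median 4712 UMIs) and 25.9% of fed neurons (991 cells, 4999 UMIs). Larvae were chosen by GCaMP6s signal in the lateral hypothalamus, but the cells came from dissociated brains and no cluster was named hypothalamic by its markers. Where in the brain the Gal4FF-high neurons lay is therefore not known here. Neurons with no Gal4FF UMI made up 57.8% (2142 cells, 3219 UMIs) and 60.3% (2304 cells, 3269 UMIs). The limit was set after the data were examined, the median Gal4FF count above it was 77.5 UMIs, and 179 neurons lay near it with 3 to 7 UMIs. Compared with neurons without Gal4FF, in the food deprived and the fed library, Gal4FF-high neurons were higher in msgn1 (6.06 and 7.56), foxg1b (4.80 and 3.67), her6 (4.62 and 3.03), the parvalbumin gene pvalb7 (3.18 and 4.03) and camk2a (3.21 and 3.29), and lower in calb2a (-3.97 and -5.39), lhx1a (-3.66 and -4.99) and tal1 (-3.31 and -3.85). ghra was higher in Gal4FF-high neurons by 2.28 and 1.71 and tac1 by 0.54 and 0.77, whereas npy (-5.75 and -7.60), galn (-6.71 and -8.62) and crhb (-3.09 and -3.30) were lower. Clusters 4 and 7 held most Gal4FF-high neurons. Of the genes above, msgn1, foxg1b, pvalb7 and camk2a are also leading genes of cluster 4, calb2a of cluster 3 and tal1 of cluster 1.

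Between fed and food deprived Gal4FF-high neurons, immediate early genes were higher in the fed library in 37 of 41 members (median 0.38). Insulin, FOXO and fasting metabolism genes were higher in 15 of 23 (0.27, percentile 100) and integrated stress response genes in 11 of 14 (0.21, 99.9). Ribosomal protein genes were lower in 83 of 92 (-0.18, percentile 0). The mix of clusters differed, with cluster 7 at 28.7% and 20.7% and cluster 6 at 18.7% and 24.3% of Gal4FF-high neurons, and with clusters weighted equally the fasting metabolism median was 0.05 and the ribosomal median -0.01. Without the kinases and rps19bp1 the pooled ribosomal median was -0.19. Genes higher in the fed library were cart4 (3 against 475 UMIs, 7.11, 5.77 to 9.61), crhbp (2.82), sst1.1 (1.58), fkbp5 (1.45), npb (1.17), nr4a3 (1.16), inhbaa (1.099), itm2cb (1.06), the histamine receptor gene hrh3 (1.03), cish (1.02, 0.69 to 1.35), pik3r3a (0.99) and nocta (0.90). Lower were oxt (1348 UMIs against 1, -9.79, -15.68 to -7.90), nppal (-1.35), znf503 (-0.74), alcamb (-0.74), adgrl1a (-0.71), smarcb1b (-0.71), b4galnt4a (-0.70), marcksa (-0.68), gbp (-0.63), tiam1a (-0.62), cox8b (-0.60) and her6 (-0.58). With clusters weighted equally cart4 was at -0.91 and nppal at 2.31. Without its 3 top cells oxt had equal counts left, and its value of 0.02 is only the ratio of the UMI totals. Of the UMIs of the higher library, 5 cells or fewer held all of those of cart4 and oxt, 99.6% of nppal, 87.4% of crhbp and 81.8% of npb. Without the 3 top cells cart4 was at 2.34, crhbp at 2.11 and nppal at -3.89. inhbaa is a leading gene of cluster 6, and itm2cb and hrh3 of cluster 16, which held 10 food deprived and 13 fed Gal4FF-high neurons. tac1 stood at 550.6 and 548.9 CPM (-0.00, -0.08 to 0.07), or -0.21 with clusters weighted equally, and in 14.4% and 17.5% of these cells. ghra was at -0.10 (-0.49 to 0.29).

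In the Gal4FF-high GABAergic-like neurons, ghra was found mainly in cells that carried tac1. Of food deprived cells with at least 2 tac1 UMIs, 43 of 78 had a ghra UMI (55.1%, 43.4 to 66.4%), against 11 of 147 cells with none (7.48%, 3.79 to 13.0%), at median depths of 4709 and 4254 UMIs. In the fed library it was 42 of 92 (45.7%, 35.2 to 56.4%) against 8 of 166 (4.82%, 2.103 to 9.27%), at 4943 and 4713 UMIs. ghra levels were 214.3 and 17.8 CPM in the food deprived library and 161.6 and 9.64 CPM in the fed library. With cells thinned to 1000 UMIs the shares were 14.1% against 2.04%, and 17.4% against 0 of 164 cells, which left out 2 cells. In cluster 6, at any Gal4FF count, it was 44 of 86 against 9 of 155 food deprived cells and 47 of 112 against 12 of 221 fed cells. The largest GABAergic-like cluster, cluster 1, had a ghra UMI in only 1.41% and 1.66% of cells, so the pattern was mainly one of cluster 6. Outside the GABAergic-like class 2 of 178 food deprived tac1-positive neurons (1.12%) and 0 of 155 fed ones, which allows up to 1.94%, had a ghra UMI. Among tac1-zero neurons there it was 34 of 2497 (1.36%) and 33 of 2502 (1.32%), so ghra was not more frequent with tac1 outside this class. Ranked by the mean log2 ratio of tac1-positive over tac1-zero cells among 2347 genes, ghra was number 4, after tac1 itself, ccka (5.69 and 5.05) and the enkephalin gene penka (4.51 and 3.45), and cish was number 10 (2.61 and 2.06). This comparison was chosen after the data were examined.

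**Figure D4:**
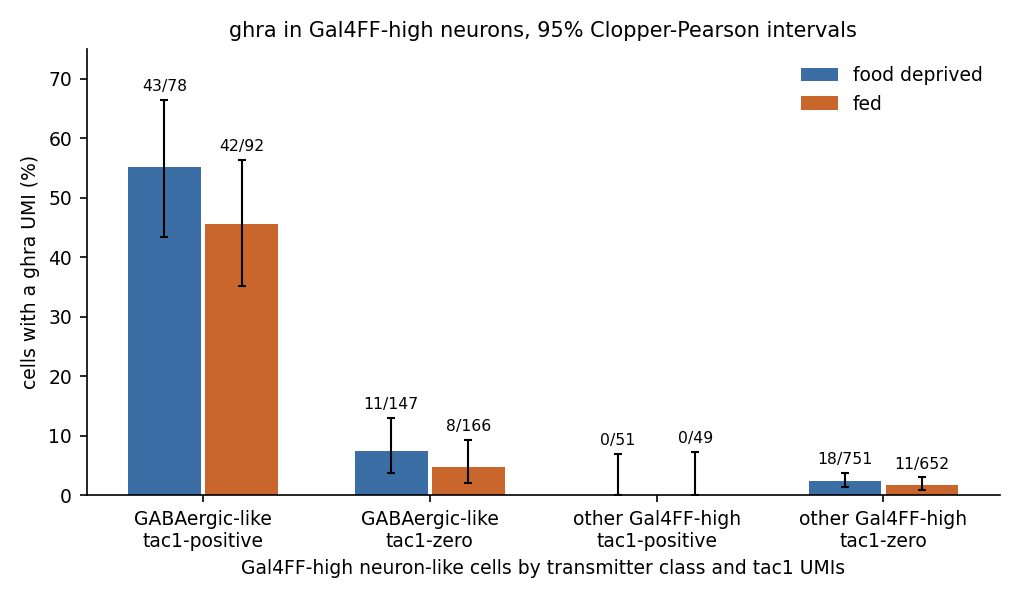
Share of Gal4FF-high neuron-like cells with a ghra UMI, in percent, by transmitter class, tac1 status (at least 2 UMIs or none) and library, with 95% Clopper-Pearson intervals and the cell counts above the bars. The tac1-positive GABAergic-like cells stand at 55.1% and 45.7%, and tac1-positive cells outside that class at 0 of 51 and 0 of 49.

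Among the feeding-related neuropeptide genes with most UMIs, the cluster with the highest CPM was cluster 10 for adcyap1b (6816 and 7882 CPM in the food deprived and fed libraries) and tac3b (1580 and 1800 CPM), cluster 1 for npy (829 and 1305 CPM) and galn (742.3 and 590.1 CPM), and cluster 26 for ccka (3618 and 10247 CPM) and tac1 (4436 and 4316 CPM). Cluster 2 held the highest level of pmchl (13149 and 1775 CPM), oxt (638.4 and 742.5 CPM) and cart4 (475.4 and 574.1 CPM), each read in under 2% of its cells. The remaining genes were highest in cluster 18 (cckb), cluster 22 (nucb2a) and cluster 3 (crhb). Of all pmchl UMIs 99.7% lay in cluster 2, of npy 88.5% in cluster 1 and of tac3b 45.8% in cluster 10. A highest CPM did not always mean most of a gene's UMIs. Cluster 26 held only 4.21% of all ccka and 3.79% of all tac1 UMIs, and cluster 22 only 5.54% of nucb2a UMIs. The CPM values of cluster 26 rest on 16 food deprived and 14 fed cells.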

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

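The tests weighed here were chosen only after the results had been seen, except the test of neuron and blood cell doublets, which was set before its value was known. The GCaMP6s transgene, by which the cells were sorted, was read outside the comparisons with 13 UMIs in the food deprived library and 15 in the fed library, above the 3 counts that a count of 0 allows, while its Gal4FF driver had 88371 and 94355 UMIs. The 3' end of the GCaMP6s reference sequence was not examined here, so its count says nothing of its expression. In 5 named genes the log2 ratio of fed over food deprived had opposite signs in Gal4FF-high and Gal4FF-zero neurons, with a size of at least 0.5 and intervals on opposite sides of 0. They were alcamb (-0.74 and 0.50), crhbp (2.82 and -0.66), her6 (-0.58 and 1.01), ptgdsb.1 (0.54 and -0.70) and tiam1a (-0.62 and 0.55). alcamb is a leading gene of cluster 7, which held 28.7% of food deprived and 20.7% of fed Gal4FF-high neurons. Most crhbp UMIs of fed Gal4FF-high neurons lay in 5 cells or fewer. These differences were not tested.

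Many of the largest ratios in neurons were those of neuropeptide genes, and few cells with very high counts are a candidate explanation for most of these ratios. In 21 of the 24 genes over 50% of the UMIs of the higher library lay in 5 cells or fewer, as a few sampled cells would give, but not in scgn (17.4%), ndufa4l2a (28.0%) and tph2 (30.2%). Unequal numbers of strongly expressing cells were less clear, since in 9 of the 24 genes the ratio of neurons with at least 10 UMIs made up over 50% of the ratio of UMIs. A change of expression with feeding in these rare cells stays open and was not tested.

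Immediate early and glucocorticoid response genes were higher in the fed library. A different mix of neuron clusters is argued against by equal weighting of the 11 clusters with at least 50 cells in each library. It left 88.8% of the pooled immediate early median and 112% of the glucocorticoid response median. Smaller clusters were left out of that weighting. Stress during dissociation that raised immediate early genes in all cell classes was tested in radial glia-like cells. The median of these genes there was -0.57, a value known before the limit for this test was written. That class held 110 food deprived and 135 fed cells, fewer than the minimum set for other classes. Its heat shock genes were also lower in the fed library, at a median of -0.34 (percentile 0.05). Both lists were lower together, so stress that differed between the libraries by cell class stays open. The immediate early value therefore counts only against a rise in every class, and cannot decide on stress. For glucocorticoid response genes stress in all classes stays open, since their median in radial glia-like cells was 0.52, above the range of random lists. Stress limited to neurons stays open too. The heat shock and protein folding list in neurons lay at percentile 95.39, between the limits set for and against it. Feeding and any other difference between the libraries cannot be told apart with 1 library per group, although feeding may raise such genes.

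Haemoglobin transcripts in neurons were higher in the fed library. Neuron and blood cell doublets are a candidate source, since 97.3% of the haemoglobin UMIs of fed neurons lay in the 1% of neurons with most of them. The complement of the same number, 2.74% outside those neurons, argues against free RNA from blood cells as the main part, so the tests are not independent. Free RNA as a lesser source stays open, as the largest difference of a haemoglobin gene's share between fed neurons and erythrocyte-like cells was 6.17 percentage points, between the limits set. Whether feeding changes the blood left in the dissected brains was not tested.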

How the results depend on the processing

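Values under alternatives named as added (cells with most UMIs, top cells of a gene, clusters 3 or 14, and those for Gal4FF-high, GABAergic-like and tac1-positive cells) were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no threshold of a test could be crossed. Over 241 results and 2429 alternative values, 2176 stayed within the counting interval or random-list range around the reported value, 228 moved beyond it, and 25 changed sign where that interval or range excluded 0. In all, 65 alternative values had the opposite sign. Some of these, named below, are only the ratio of UMI totals where equal counts were left. The immediate early median in neurons ranged from 0.24 to 0.28 over 16 alternatives, that of insulin, FOXO and fasting metabolism from 0.07 to 0.15, that of glucocorticoid response from 0.09 to 0.23 and tac1 from -0.22 to -0.09 over 15. For each value below the cause was not tested, except where leaving out a gene's top cells or a cluster shows that the value rested on them. Genes with few UMIs and cell shares at thinned depth are limited by counting.

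With cells thinned to 1000 UMIs the neuron medians were 0.16 for the growth hormone axis, 0.12 for orexigenic neuropeptides (a change of sign), 0.093 for glucocorticoid response and 0.11 for sterol synthesis, tac1 was at -0.16, and tac3a (-0.13), galn (1.06) and cckb (0.072) changed sign. With clusters weighted equally the medians were -0.10 for orexigenic neuropeptides, 0.14 for heat shock and -0.0052 for ribosomal proteins, tac1 was at -0.22, and mt2 (0.23), nr3c1 (-0.0085), hsp70l (0.026), mt-co3 (0.0011) and rps21 (0.013) changed sign. With members of at least 100 UMIs the anorexigenic median was 0.089. With all variable genes pde6gb was at 0.013. The tac1 shares of neurons thinned to 500 UMIs were 5.73% and 5.24% in the food deprived and fed libraries, and thinned to 2000 UMIs 8.84% and 8.53%.

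Without the 5% of cells with most UMIs the medians were -0.088 for orexigenic and -0.10 for anorexigenic neuropeptides, the neuron-like shares were 87.4% and 86.2%, and CARTPT (-0.46), pmchl (0.49) and pde6gb (0.027) changed sign. Without cluster 3 the anorexigenic median was 0.10, and pde6gb (0.037) and cckb (0.30) changed sign. Without cluster 14 ndufa4l2a (0.22) and mt2 (0.16) did. Without the 3 cells with most UMIs of the gene, CARTPT (-0.076), pmch (-0.076), pde6gb (0.019) and galn (0.88) did, and oxt (0.020) in Gal4FF-high neurons. For CARTPT, pmch and oxt the counts left were equal in both libraries. Their values are then only the ratio of the UMI totals and show no reversed difference. In Gal4FF-high neurons with clusters weighted equally the medians were 0.31 for immediate early genes and -0.0084 for ribosomal proteins. That of insulin, FOXO and fasting metabolism was 0.051, tac1 was at -0.21, and cart4 (-0.91) and nppal (2.31) changed sign. With at least 20 Gal4FF UMIs tac1 was at 0.11. In GABAergic-like neurons with clusters weighted equally tac1 was at -0.36. Over all cells CARTPT (-0.059) changed sign without its 3 top cells, where equal counts were again left.

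The share of tac1-positive Gal4FF-high GABAergic-like neurons with a ghra UMI was 14.1% and 17.4% (food deprived and fed) with cells thinned to 1000 UMIs, 32.5% and 27.5% thinned to 2000 UMIs, and 16.96% and 16.7% over all neuron-like cells. In tac1-zero cells it was 2.04% and 0% thinned to 1000 UMIs, 3.47% thinned to 2000 UMIs in the food deprived library, and 1.66% and 1.77% over all neuron-like cells. No cluster was pituitary-like, so only cells with a pou1f1, prl, pomca or cga UMI were left out. Keeping called doublets gave no further values, since none were removed, nor did gh1 shares, since gh1 had 0 UMIs.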

Other observations

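Comparisons in this part were chosen after the data were examined, except those of blood, photoreceptor, epidermal and microglial markers, and no explanation is offered for them. cish, a STAT5 target that is induced downstream of the growth hormone receptor, was higher in the fed library in Gal4FF-high neurons with 236 against 118 UMIs. By cluster it stood at 107.2 against 49.8 CPM in GABAergic-like cluster 6 (log2 ratio 1.098, 0.67 to 1.57), at 0.89 (0.45 to 1.37) in cluster 10, at 1.38 (0.66 to 2.202) in cluster 1, at 0.65 in cluster 4, at 0.72 in the unnamed cluster 8 and at 0.68 (0.21 to 1.16) in radial glia-like cells. Cluster 2 went the other way at -0.56 (-1.08 to -0.05), with 86 and 53 UMIs. In every other cluster with at least 50 cells in each library the interval included 0, with cluster 11 at -0.28 (-1.37 to 0.89), cluster 14 at -0.27 (-2.52 to 1.48) and the unnamed cluster 13, with most cish UMIs (116 and 201), at 0.24 (-0.09 to 0.59). In Gal4FF-high GABAergic-like cells, tac1-positive cells had 120.2 CPM of cish in the food deprived and 186.8 CPM in the fed library (0.63, 0.11 to 1.18), and tac1-zero cells 19.2 and 44.6 CPM (1.19, 0.30 to 2.22). In the tac1-positive cells tac1 itself was at -0.38 (-0.48 to -0.29) and ghra at -0.41 (-0.88 to 0.06). These cells were chosen by their tac1 UMIs, so the tac1 value depends on that choice. fosab was at 0.53 in tac1-positive and 0.12 in tac1-zero cells, npas4a at 0.52 and 0.39 and fkbp5 at 1.29 and 0.97. Whether these cells differ from each other was not tested.

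Neurons with no Gal4FF UMI had an immediate early median of 0.24 (33 of 41 members higher in the fed library). Their glucocorticoid response median was 0.17, and that of insulin, FOXO and fasting metabolism 0.15. Oxidative phosphorylation genes were lower in 29 of 35 members at -0.09, and ribosomal protein genes had a median of -0.00. tac1 was at -0.23 (-0.31 to -0.16), tac3b at 0.74 and kiss2 at -5.21, with 387 UMIs against 11. Of the 387 kiss2 UMIs 97.2% lay in 5 cells, and without the 3 top cells kiss2 was at -2.46. ccka was at -1.78 (-1.86 to -1.70), with 5318 against 1707 UMIs in 97 and 72 cells, or -2.01 without the 3 top cells, whereas in Gal4FF-high neurons it was at 0.32 (0.26 to 0.38). Over all cells, neurons included, transcripts of other tissues differed between the libraries. Photoreceptor or pineal markers were at 2.38, haemoglobin genes at 1.53 and epidermal markers at 1.04. A group of pigment and skin genes stood at 3.18 and liver genes at -7.97, and microglial markers at -0.31.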
